A study of Mus musculus with 12 samples.

How the data were processed

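RNA was measured in 12 libraries of Treg sorted as live, TCRβ, CD4, GFP and CD25 positive cells from 21-day-old male mice, 3 libraries in each of 4 groups (spleen WT, spleen ∆Foxp3, lung WT and lung ∆Foxp3). Per the labels' protocols, spleens were dissociated mechanically, while lungs were perfused, digested with collagenase and DNase and enriched for CD4 T cells by negative magnetic selection. Red cells were lysed, in a step whose tissue the protocol does not name. Per the same protocols, 1000 cells per library were sorted again into lysis buffer. Polyadenylated RNA was copied with an oligo(dT) primer, fragmented by Tn5 and amplified for 18 cycles with no molecular identifiers, and paired reads of 38 nt were taken. Per the submitters' processing notes, STAR 2.7.3a, featureCounts, Subread 2.0.0 and the mouse build mm10 were used; their settings, the gene annotation and the strand setting are not given in the sources used here.

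The authors deposited raw counts per gene symbol, whole numbers in 1 table of 55011 genes by 12 libraries, which were used as they stood. Every gene symbol was kept as the table gives it. Of the symbols, 52936 (96.2%) matched the annotation of the same build, from which coordinates were taken; 98.2% of the tested genes did so. Library totals were 3958892 to 9025150 counts, and a floor of 3 counts in a library corresponds to 0.332 to 0.758 CPM. Reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only.

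Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with robust dispersion, TMM factors and its default low-count filter by group (13295 genes tested). The group was the only term, in 1 fit over the 12 libraries, so that groups of 3 share an estimate of spread. The 6 contrasts were ∆Foxp3 minus WT in spleen, the same in lung, lung minus spleen in WT, the same in ∆Foxp3, their interaction and the average of the genotype contrasts. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Log2 fold changes carry standard errors of the fit, and group levels are TMM-scaled CPM with SD. Where a group had 0 counts in all libraries, the fold is a lower bound against 3 counts over the group, and where it had 1 to 3, a pooled ratio with an exact 95% binomial (Clopper-Pearson) interval. The overlap of calls used Fisher's exact test.

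The comparisons, the alternatives below, the 33 gene lists and the rule for named genes were set before the data were examined. Named genes were, per contrast, up to 8 higher and 8 lower with the largest changes among called genes with a mean of 10 CPM or more whose groups did not overlap (for the interaction and the average, without that last condition). Predicted genes, pseudogenes and receptor segments were left out. Also named were Foxp3, Il2ra, Cd4, Trbc1, Trbc2 and Cd3e, up to 4 called members of each list by adjusted p, or the 2 most abundant where none passed, and the 4 smallest adjusted p of the interaction. The lists were Treg signature, naive and resting T cell, effector and tissue Treg, T helper cytokines, Th1, Th2, Th17 and follicular helper programs, type I interferon and interferon gamma response, cell cycle, glycolysis and hypoxia, cholesterol synthesis, oxidative phosphorylation, immediate early genes, heat shock and dissociation stress, co-inhibitory receptors, IL-2 and STAT5 targets, homing and adhesion receptors, cytotoxic granule, apoptosis regulators, ribosomal protein, mitochondrial encoded genes, and markers of 10 kinds of other cells. Some genes are in more than 1 list. Lists were tested with camera (preset correlation 0.01, and again with an estimated correlation), which sets a list against the other genes, using limma 3.58.1 and adjustment over the 32 lists with a tested member. The fry test was also run, whose p asks whether a list's genes move on balance in a common direction and compares no lists. Of the 79 camera calls over the 6 contrasts, 1 held with an estimated correlation.

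Alternatives were RLE and upper-quartile factors, library totals without TMM, no low-count filter, 10 CPM or more in 3 libraries, DESeq2 1.42.0 and limma voom with sample quality weights. Further alternatives were edgeR without robust dispersion, a test against a fold of 1.5 (glmTreat), only the groups compared in the fit, the replicate number as a block (also nested in genotype), leaving out mitochondrial, ribosomal and receptor genes, thinning to the smallest total, and leaving out each library. After seeing the data, leaving out Gm10800 and Gm10801, and leaving out spleen WT 1, lung WT 1 and lung ∆Foxp3 3, were added. Genes that the text names in a comparison outside the rule were also followed under these alternatives. Ranges of an adjusted p over the alternatives leave out the test against a fold and the estimated correlation. Results for some single genes are not reported here. No pairing by replicate number was used in the main tests.

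The functions were tested on simulated counts with the real totals and dispersions and each gene's mean over the 12 libraries. In these counts, 200 genes changed by 1.5-, 2-, 4- or 8-fold (50 genes each). For the simulated spleen genotype contrast (12815 genes), edgeR called 0%, 22%, 76% and 72% of them, and for the lung genotype (12821 genes) 0%, 30%, 76% and 76%. For the tissue in WT (12803 genes) it called 6%, 22%, 66% and 82%, and for the tissue in ∆Foxp3 (12838 genes) 2%, 20%, 60% and 74%. For the interaction (12818 genes) it called 4%, 12%, 48% and 62%, and for the average (12814 genes) 18%, 52%, 70% and 88%. No call of a changed gene had the wrong direction. In the spleen contrast it made 6 false calls, 6.59% of its calls, while DESeq2 made 29, or 22.0%. In the interaction they made 2 (3.08%) and 18 (18.9%). The real genotype contrasts called far more than 200 genes, so these shares need not carry over to them. The recovery that the simulation had first been required to reach was missed by limma and by the nested block for 8-fold interaction changes, and this requirement was replaced by a requirement on fitted sizes, directions and edgeR's false calls. Figures were drawn with matplotlib 3.10.9.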

Results

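Regulatory T cells (Treg), CD4 T cells that restrain immune responses and rely on the transcription factor Foxp3, were profiled in the spleen and lungs of 21-day-old male C57BL/6 mice. WT Treg carried an intact Foxp3 gene with a GFP reporter. ∆Foxp3 Treg carried a Foxp3 gene that the labels mark as deleted, also with a green reporter. Cells of both genotypes could thus be sorted by the same gate (live, TCRβ, CD4, GFP and CD25 positive). The 4 groups, spleen WT, spleen ∆Foxp3, lung WT and lung ∆Foxp3, had 3 libraries each, made from 1000 sorted cells per library by Smart-seq2, which copies and amplifies polyadenylated RNA. Library totals ran from 3958892 to 9025150 counts. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical. They give the spleen ∆Foxp3 libraries another allele (an EGFP and Cre fusion, with a YFP reporter at the Rosa26 locus) than the lung ∆Foxp3 libraries. The protocol in the same labels names only the allele of the lung libraries for both tissues, so the sources disagree on whether the alleles differ.

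The first principal component, with 46.2% of the variance, separated the genotypes, and the second, with 14.9%, separated the lung from the spleen libraries. Spleen WT 1 stood apart on the second component, at −62.6, and in the share of counts in Gm10800 and Gm10801, predicted genes rich in repeats, which was 0.112% there and 0.743% to 2.94% in the other 11 libraries. Lung WT 1 and lung ∆Foxp3 3 detected the most genes of their groups, 22981 and 23649, and lung ∆Foxp3 3 held 2.44% mitochondrial counts. These 3 libraries are called the libraries that stand apart, a choice made after seeing the data. For every gene given below as changed in a comparison of 2 groups, the 3 libraries of a group lay all above or all below the 3 of the other, unless stated.

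**Figure D1:**
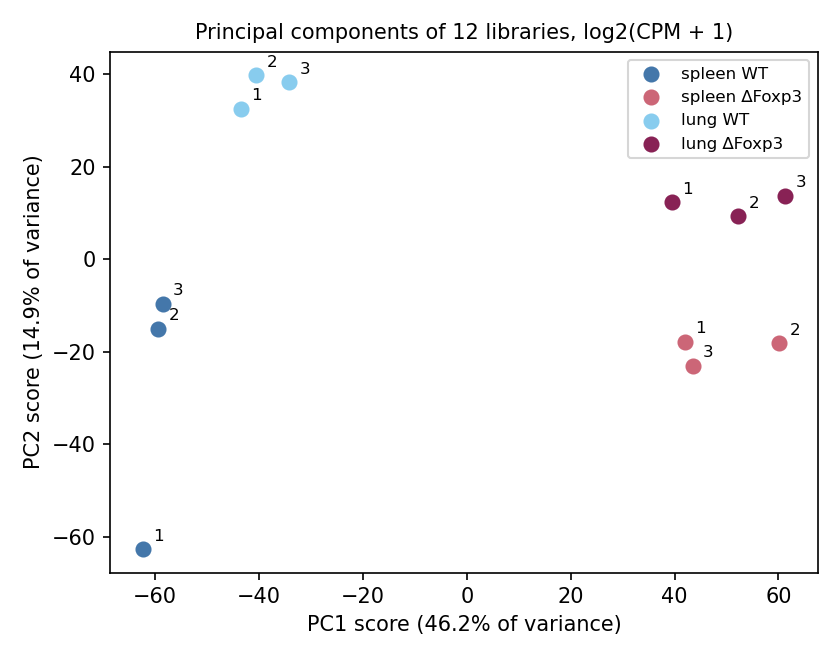
Scores of the 12 libraries on the first and second principal components of log2(CPM + 1), with points coloured by group and numbered by replicate. The 6 ∆Foxp3 libraries lie at PC1 scores of 39.4 to 61.3 and the 6 WT libraries at −62.4 to −34.2.

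Foxp3 itself (chromosome X, 7573644 to 7595245, mm10) was counted at 1026, 991 and 1096 CPM (counts scaled to a common library total) in the spleen WT libraries and at 159, 114 and 227 CPM in spleen ∆Foxp3. In lung it was at 1418, 1361 and 1328 CPM in WT and at 469, 385 and 189 CPM in ∆Foxp3. The log2 fold change was −2.64 ± 0.29 (SE; adjusted p = 2.9e-05) in spleen and −1.98 ± 0.28 (adjusted p = 0.00041) in lung. Which part of the gene the alleles lack is not given in the sources used here, so reads from parts that remain can enter these counts. Il2ra, the CD25 of the sorting gate, fell by 1.02 ± 0.23 on the log2 scale in spleen (adjusted p = 0.00531). Its difference in lung was −0.49 ± 0.23 (adjusted p = 0.156). That p was 0.0373 without a low-count filter, 0.0440 with limma and 0.0359 with only the lung libraries in the fit, and ran from 0.0359 to 0.645 over all alternatives. Since CD25 was part of the gate, a change in Il2ra is bounded by the sort. Trbc2, a constant segment of the T cell receptor, fell by 0.71 ± 0.14 in spleen (adjusted p = 0.00176) and by 0.66 ± 0.14 in lung (adjusted p = 0.00456).

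Genes that differ between the genotypes in splenic Treg were sought by comparing spleen ∆Foxp3 with spleen WT. In either tissue, effects of the allele in the cells cannot be told apart from effects of the surroundings in ∆Foxp3 mice. Il4, which encodes the type 2 cytokine interleukin 4 (chromosome 11, 53602982 to 53618669), had 0 counts in the 3 WT libraries and 54.5 ± 48.9 CPM in the 3 ∆Foxp3 libraries (SD, n = 3), at least 351-fold higher against a floor of 3 counts over the group (adjusted p = 0.000515). Lilr4b, a leukocyte immunoglobulin-like receptor gene, was at least 1163-fold higher by the same floor (adjusted p = 0.00216), with the reservation that its reads can be shared with its close paralog Lilrb4a. Gzma, which encodes the protease granzyme A, had 3 counts in all over the WT libraries and 80.0 ± 28.2 CPM in ∆Foxp3, a ratio of 543 (95% counting interval 185 to 2637; adjusted p = 8.6e-05). Cd55, a regulator of complement, fell by 4.78 ± 0.28 on the log2 scale (adjusted p = 3.7e-07), Slc28a2b, a nucleoside transporter gene, by 5.27 ± 0.59 (adjusted p = 2.9e-05), and Gbp2b, a guanylate-binding protein gene, by 4.88 ± 0.72 (adjusted p = 0.000262). In all, 3540 of 13295 genes passed the test, 1878 higher and 1662 lower in ∆Foxp3, of which 2200 changed by more than 2-fold.

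The cell cycle genes rose together in spleen ∆Foxp3: all 36 were higher, also when adjusted over the list alone. Kif11, a mitotic spindle motor, rose by 4.51 ± 0.32 and Ccna2, cyclin A2, by 3.63 ± 0.31 (camera adjusted p = 8.8e-49; adjusted p = 0.16 with an estimated correlation). Of 21 glycolysis and hypoxia genes, 15 rose and 1 fell, likewise adjusted over the list alone, with Tpi1 at 2.81 ± 0.26 and Pgk1 at 2.03 ± 0.20 (camera adjusted p = 7.7e-09; adjusted p = 0.16 with an estimated correlation). Of 29 type I interferon response genes, 19 fell, 10 did not pass and 0 rose, with 23 lower adjusted over the list alone. Rsad2, an antiviral enzyme gene, fell by 4.24 ± 0.56 and Rtp4 by 2.34 ± 0.27 (camera adjusted p = 1.0e-11; adjusted p = 0.209 with an estimated correlation). Of 18 naive and resting T cell genes, 12 fell and 2 rose, and 13 and 2 did so adjusted over the list alone. Id3, a transcriptional regulator, fell by 2.76 ± 0.17, while Themis, a T cell receptor signalling gene, rose by 1.55 ± 0.16 (camera adjusted p = 1.9e-07; adjusted p = 0.16 with an estimated correlation). By fry, the cell cycle genes moved up on balance (adjusted p = 0.000892) and the type I interferon genes down (0.00159). The mitochondrial share of counts was 1.51% ± 0.106 in WT and 1.52% ± 0.0909 in ∆Foxp3 (SD, n = 3).

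Of 30 Treg signature genes in spleen, 15 fell, 5 rose and 10 did not pass, with 17 lower and 5 higher adjusted over the list alone. Lrrc32, the surface anchor of latent TGF-β, fell by 2.97 ± 0.44, and Tigit, an inhibitory receptor, rose by 1.74 ± 0.18 (camera adjusted p = 0.00159; adjusted p = 0.543 with an estimated correlation). Of 24 effector and tissue Treg genes, 14 rose and 0 fell, and 18 rose and 2 fell adjusted over the list alone. Id2 and Maf, both transcriptional regulators, rose by 3.83 ± 0.36 and 1.78 ± 0.19 (camera adjusted p = 1.3e-07; adjusted p = 0.16 with an estimated correlation). Of 13 T helper cytokines, 8 were higher and 2, Tnf and Lta, lower, the same number lower and 9 higher adjusted over the list alone (adjusted p of Tnf 0.00706, and 3.0e-06 to 0.0547 over the alternatives, the last without the libraries that stand apart). The list median was 4.17, or 3.16 with the 4 genes at 0 in WT set to their bound (camera adjusted p = 0.0192; adjusted p = 0.543 with an estimated correlation). That call also ended at 10 CPM or more in 3 libraries, with limma and with only the spleen libraries in the fit (adjusted p = 0.133 to 0.303, and 0.000644 to 0.303 over all alternatives). Of 16 Th1 genes, 9 rose and 1 fell, with 12 and 1 adjusted over the list alone, among them Nkg7, a cytotoxic granule gene, at 3.53 ± 0.38 (camera adjusted p = 1.5e-05; adjusted p = 0.16 with an estimated correlation). Of 14 Th2 genes, 11 rose and 2 fell, the same adjusted over the list alone, among them Pparg, a lipid-sensing nuclear receptor, at 3.36 ± 0.46 (camera adjusted p = 9.6e-05; adjusted p = 0.209 with an estimated correlation). Of 14 cytotoxic granule genes, 5 rose and 0 fell, with 6 and 0 adjusted over the list alone (camera adjusted p = 0.000417; adjusted p = 0.26 with an estimated correlation).

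Markers of other cells moved in places with these groups. The summed B and plasma cell markers were 1158 to 1382 CPM in spleen WT, most of it Ighm, and 233 to 501 CPM in spleen ∆Foxp3. Ighm fell by 3.51 ± 0.34 (adjusted p = 1.5e-05) and was at 130, 134 and 50.5 CPM in the spleen ∆Foxp3 libraries. Of 8 B and plasma cell genes tested, 2 were higher and 3 lower, and 3 and 4 adjusted over the list alone (camera adjusted p = 0.147). The summed erythroid and platelet markers were 11.3 to 19.0 CPM in WT and 14.1 to 487 CPM in ∆Foxp3, where ∆Foxp3 1 had 0.0359% hemoglobin counts. The summed endothelium markers, mostly Pecam1, were 465 to 519 CPM in WT and 157 to 200.4 CPM in ∆Foxp3. Fibroblast and smooth muscle markers, among which Fn1 was the most abundant over the 12 libraries, were at 7.15 to 8.24 CPM and 25.7 to 29.5 CPM. Such sums do not show whether the RNA came from other cells or from the sorted Treg. Of the 3540 genes, 3369 had groups that did not overlap; over all tested genes, 38.2% did not overlap, where chance gives 10%. The count was 2287 when only the spleen libraries entered the fit and 1648 against a fold of 1.5.

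In the lungs, Il4 was at 0 counts in the 3 WT libraries and at 125 ± 29.6 CPM in ∆Foxp3, at least 585-fold higher (adjusted p = 0.000611). Il13, the gene of another type 2 cytokine (chromosome 11, 53631324 to 53634702), was likewise at 0 in WT and at 29.0 ± 14.5 CPM in ∆Foxp3, at least 137-fold higher (adjusted p = 0.0133, and 5.7e-05 to 0.0902 over the alternatives, the last without the libraries that stand apart). Il12rb2, a chain of the interleukin 12 receptor, had 1 count over the WT libraries and 22.4 ± 18.4 CPM in ∆Foxp3, a ratio of 332 (95% counting interval 59.1 to 13147; adjusted p = 0.000812). Ccr10, a chemokine receptor gene, fell by 6.09 ± 1.04 (adjusted p = 0.00125), Gbp2b by 5.93 ± 0.77 (adjusted p = 0.000192) and Rsad2 by 5.89 ± 0.62 (adjusted p = 3.4e-05). In all, 2686 genes passed, 1295 higher and 1391 lower in ∆Foxp3, and 1608 of them changed by more than 2-fold. The count was 1692 without lung WT 1, 1554 without lung WT 2, 1596 without lung ∆Foxp3 2, 1457 without lung ∆Foxp3 3 and 1321 without the 3 libraries that stand apart. It rose to 3922 with only the lung libraries in the fit and to 4627 with limma.

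Of 29 type I interferon response genes, 23 fell and 0 rose in lung ∆Foxp3, with 24 lower adjusted over the list alone (camera adjusted p = 2.1e-16; adjusted p = 0.107 with an estimated correlation), and Trim30a fell by 1.34 ± 0.14. Of 19 interferon gamma response genes, 6 rose and 0 fell, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.136). The camera p was 0.0223 without lung WT 1, 0.00554 without lung ∆Foxp3 3, 0.00109 without the libraries that stand apart and 0.0202 without a low-count filter, within a range of 0.00109 to 0.315 over the alternatives. In spleen, 3 of these fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.141; 0.00547 without spleen ∆Foxp3 2 and 0.0483 without a low-count filter; 0.00547 to 0.343 over the alternatives). Of 18 naive and resting T cell genes, 12 fell and 2 rose, with 13 and 2 adjusted over the list alone. S1pr1, the receptor that lets T cells leave lymphoid tissue, fell by 1.78 ± 0.21 (camera adjusted p = 1.1e-09; adjusted p = 0.107 with an estimated correlation). Of 36 cell cycle genes, 19 rose and 0 fell, with 29 higher adjusted over the list alone and Kif11 at 1.44 ± 0.27 (camera adjusted p = 3.0e-11; adjusted p = 0.258 with an estimated correlation). Of 21 glycolysis and hypoxia genes, 11 rose and 1 fell, with 12 and 1 adjusted over the list alone and Aldoa at 1.59 ± 0.18 (camera adjusted p = 1.2e-05; adjusted p = 0.194 with an estimated correlation).

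Of the 13 T helper cytokines, 8 rose in lung ∆Foxp3 and 0 fell, with 9 higher adjusted over the list alone, among them Ifng at 4.07 ± 0.71 and Il10 at 4.02 ± 0.62. The list median was 4.02, or 3.94 with the 4 genes at 0 in WT set to their bound (camera adjusted p = 4.9e-08; adjusted p = 0.107 with an estimated correlation). Of 14 Th2 genes, 10 rose and 2 fell, the same adjusted over the list alone, with the chemokine receptor gene Ccr8 at 2.49 ± 0.28 (camera adjusted p = 8.3e-08; adjusted p = 0.107 with an estimated correlation). Of 16 Th1 genes, 7 rose and 0 fell, with 8 and 0 adjusted over the list alone (camera adjusted p = 1.9e-06; adjusted p = 0.107 with an estimated correlation). Of 14 cytotoxic granule genes, 8 rose and 0 fell, with 11 and 1 adjusted over the list alone and Fasl, the ligand of the death receptor Fas, at 4.58 ± 0.78 (camera adjusted p = 6.9e-07; adjusted p = 0.107 with an estimated correlation). Of 24 effector and tissue Treg genes, 13 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 3.5e-09; adjusted p = 0.107 with an estimated correlation). The Treg signature divided, with 6 of 30 genes lower and 5 higher, and 7 and 5 adjusted over the list alone (camera adjusted p = 0.468). Of 28 immediate early genes, 7 rose and 1 fell, with 10 and 1 adjusted over the list alone and Egr1 at 1.49 ± 0.24 (camera adjusted p = 0.000161; adjusted p = 0.258 with an estimated correlation). In spleen, 2 of these rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.0920). That p was 0.0289 without spleen WT 3, 0.0430 without spleen ∆Foxp3 2, 0.0310 without lung WT 1, 0.0057 without a low-count filter and 0.0367 with only the spleen libraries in the fit, within 0.0057 to 0.248 over the alternatives.

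Beside these groups, the lung WT libraries held 0.181% to 0.452% hemoglobin counts and the lung ∆Foxp3 libraries at most 0.0350%. Of 8 erythroid and platelet genes, 3 were lower in lung ∆Foxp3 and 7 were lower adjusted over the list alone (camera adjusted p = 0.00105; adjusted p = 0.258 with an estimated correlation). Of 8 B and plasma cell genes, 3 were lower, also adjusted over the list alone (camera adjusted p = 0.00147; adjusted p = 0.107 with an estimated correlation). The call ended without the mitochondrial, ribosomal and receptor genes (adjusted p = 0.437, the highest of the alternatives, from 0.000155). That setting removes Ighm, the most abundant marker of this list. Ighm fell by 3.56 ± 0.34 (adjusted p = 2.8e-05). Of 6 endothelium genes, 2 were lower, also adjusted over the list alone (camera adjusted p = 0.0304; adjusted p = 0.157 with an estimated correlation; 0.0829 without lung WT 3 and 0.178 with limma, and from 0.00125 over the alternatives). These were Pecam1, at −1.42 ± 0.17, and Ly6c1, at −3.72 ± 0.43, which the naive T cell list also holds. The summed endothelium markers were 424 to 530 CPM in WT and 172 to 183 CPM in ∆Foxp3. Lung epithelium markers were at 63.7 to 241 CPM and 27.8 to 39.5 CPM. Monocyte, macrophage and dendritic cell markers were at 400 to 776 CPM and 331 to 393 CPM. Over the 12 libraries, Epcam was the most abundant of the former and Ctss of the latter. These sums, too, do not show which cells the RNA came from. Of the 2686 genes, 2654 had groups that did not overlap; over all tested genes the share was 45.3%, where chance gives 10%.

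**Figure D2:**
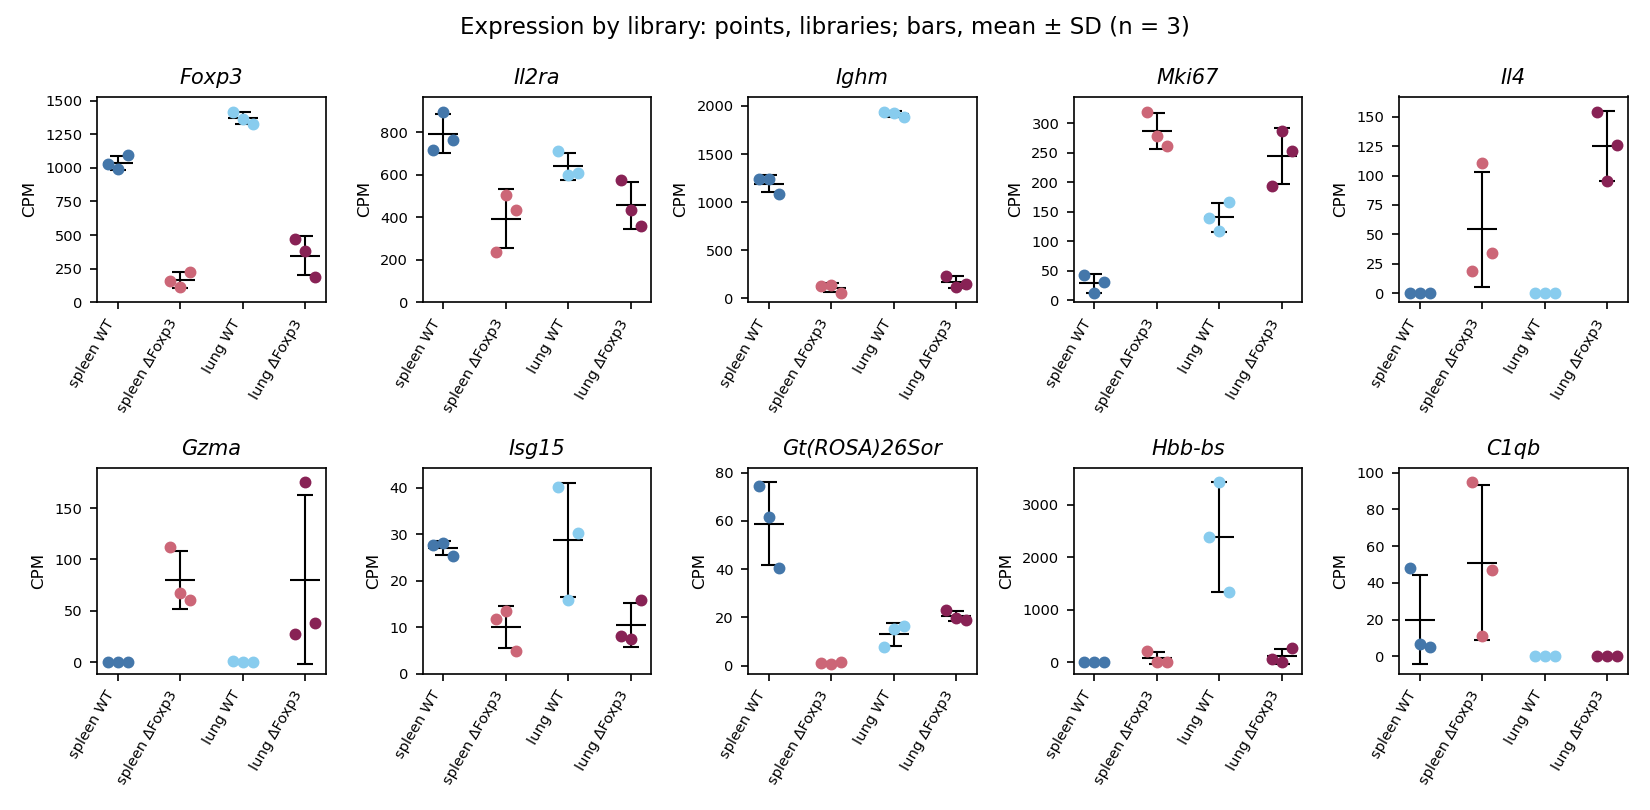
Levels of 10 genes in CPM (linear axes) by group, with each point a library and bars giving the mean and SD (n = 3). Foxp3 and Ighm lie lower in both ∆Foxp3 groups, and Gt(ROSA)26Sor is near 0 in spleen ∆Foxp3 alone, at 0.955 ± 0.423 CPM.

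The genotype differences of the spleen and the lung were set against each other. The comparisons share no library, although both use each gene's spread from the same fit. In both, 909 genes were higher and 955 lower, 1864 in all, against 183 and 174 by chance (Fisher's exact test, odds ratio 26.8, 95% interval 23.3 to 30.8, and 34.7, 30.2 to 39.9). Fisher's test takes genes as independent, and the chance counts leave out the shared spread. The 1864 became 1181 without lung WT 2, 1221 without lung ∆Foxp3 2, 1146 without lung ∆Foxp3 3 and 995 without the 3 libraries that stand apart. Across the 13295 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.675 and Spearman's rho 0.693. The genes called in opposite directions numbered 10, among them Btg2, Egr1 and Tnf. The call of Egr1 in spleen (adjusted p = 0.0486) was lost under most alternatives, with the highest p, 0.218, without spleen WT 2. That of Tnf in lung (adjusted p = 0.0300) was lost without lung WT 1, 2 or 3 or lung ∆Foxp3 2 or 3 (0.0592 to 0.101) and without the libraries that stand apart (0.114). Averaged over the tissues, 5209 genes differed between the genotypes, 2682 higher and 2527 lower in ∆Foxp3. Cd55 had the smallest adjusted p among those named, at −4.42 ± 0.20 (adjusted p = 6.9e-09), and H2-Ob, a gene of the MHC class II family, fell by 4.24 ± 0.41 (adjusted p = 8.6e-06).

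**Figure D3:**
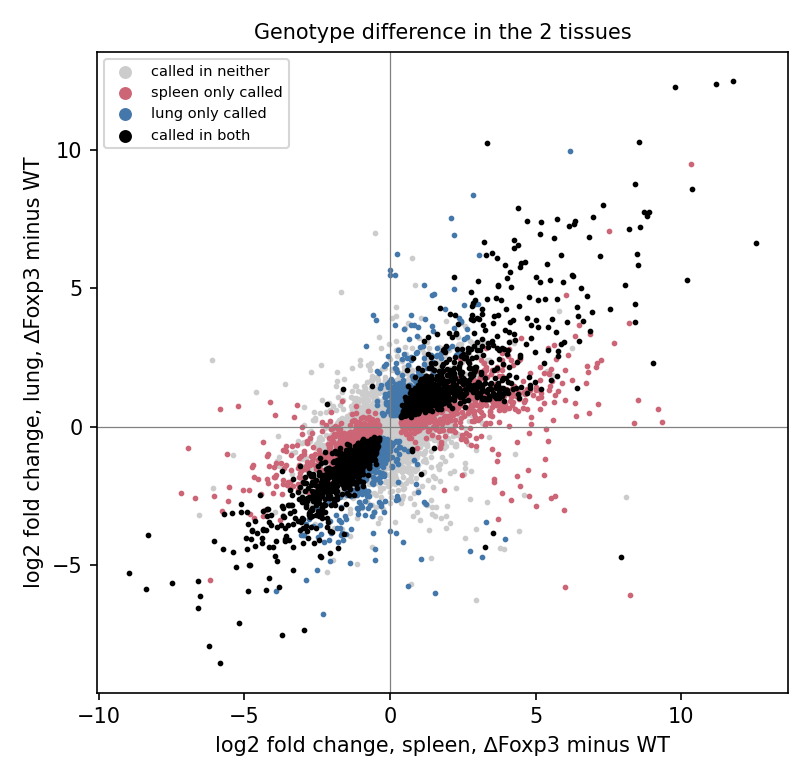
Log2 fold change of ∆Foxp3 minus WT for 13295 genes in spleen (x axis) and lung (y axis), with each point a gene, coloured by the tissues in which it passed an adjusted p under 0.05. Most genes called in both, in black, lie in the lower left (955) and upper right (909) quadrants; the far points belong to genes at 0 in a group, whose fitted values are not bounds.

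**Figure D4:**
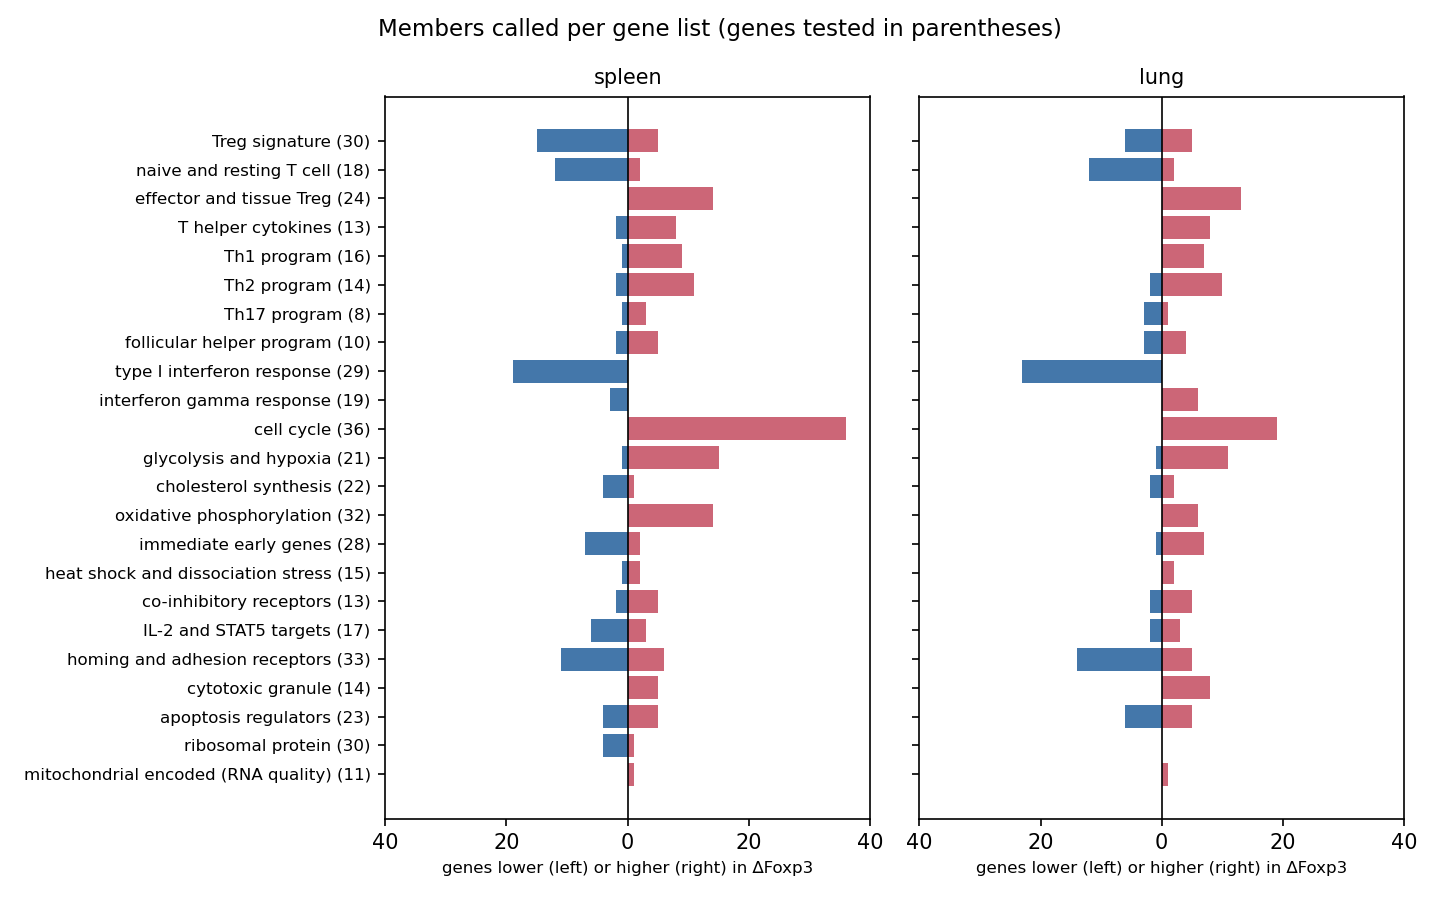
Members of each gene list called lower (blue, left) or higher (red, right) in ∆Foxp3 in spleen and lung; the x axes count genes and the number tested stands in parentheses. Of the 36 cell cycle genes, 36 were higher in spleen and 19 in lung.

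How Treg differ between lung and spleen was addressed within each genotype. In WT, Ctse, which encodes the protease cathepsin E, was at 519 ± 68.2 CPM in spleen and 27.5 ± 1.33 CPM in lung (SD, n = 3; log2 fold change −4.23 ± 0.29, adjusted p = 5.5e-06). Egr2, a transcription factor gene induced by receptor signalling, fell by 5.86 ± 0.54, to 0.867 ± 0.861 CPM (adjusted p = 7.3e-05). Hspa1a, an inducible heat shock gene, rose from 0.854 ± 1.48 to 131 ± 30.7 CPM (adjusted p = 0.000432), with the reservation that its reads can be shared with Hspa1b. Of 36 cell cycle genes, 30 were higher in lung and 36 adjusted over the list alone, with Kif11 at 3.22 ± 0.31 (camera adjusted p = 4.9e-55; adjusted p = 0.0633 with an estimated correlation). In all, 549 genes differed, 412 higher and 137 lower in lung, with 547 showing no overlap; 25.6% of tested genes did not overlap, where chance gives 10%. The count was 320 without spleen WT 2, 325 without lung WT 2 and 281 without lung WT 3, and with library totals in place of TMM 371 were higher and 260 lower. The 137 lower genes became 74 and 73 without spleen WT 1 and 2, 207 without spleen ∆Foxp3 2, and 86, 49 and 45 without lung WT 1, 2 and 3.

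Of 33 homing and adhesion receptors, 4 were higher in lung WT, 6 higher and 1 lower adjusted over the list alone, among them the chemokine receptor gene Ccr4 at 1.30 ± 0.24 (camera adjusted p = 0.000206; adjusted p = 0.0633 with an estimated correlation). Of 24 effector and tissue Treg genes, 4 were higher, with 10 higher and 1 lower adjusted over the list alone, among them Nfil3 at 3.52 ± 0.48 and Il1rl1, the interleukin 33 receptor, at 1.86 ± 0.32 (camera adjusted p = 2.6e-05; adjusted p = 0.169 with an estimated correlation). Of 15 heat shock and dissociation stress genes, 3 were higher, and 6 adjusted over the list alone (camera adjusted p = 0.000334; adjusted p = 0.528 with an estimated correlation). The immediate early genes divided, with 7 of 28 higher and 4 lower, and 10 and 5 adjusted over the list alone. Tnfaip3, a brake on NF-κB signalling, was at 2.89 ± 0.28 and Egr1 at −2.20 ± 0.24 (camera adjusted p = 0.265; 0.00651 without lung WT 3, and up to 0.883 over the alternatives). The lungs alone were digested with warm enzymes and enriched by magnetic beads, so this handling and the tissue are the same split of the libraries. Beside these groups, the summed erythroid and platelet markers were 1986 to 4921 CPM in lung WT and 11.3 to 19.0 CPM in spleen WT. Of 8 such genes, 4 were higher in lung, and 7 adjusted over the list alone, with a median of 7.43, or 6.72 with the gene at 0 set to its bound (camera adjusted p = 5.9e-07; adjusted p = 0.169 with an estimated correlation). Of 4 fibroblast and smooth muscle genes, 2 were higher, and 3 adjusted over the list alone (camera adjusted p = 0.00257; adjusted p = 0.169 with an estimated correlation). That call ended at 10 CPM or more in 3 libraries (0.0974) and with DESeq2 (0.151), within 0.000412 to 0.151 over the alternatives. Of 8 lung epithelium genes, 1 was higher, and 3 adjusted over the list alone (camera adjusted p = 0.0391; adjusted p = 0.169 with an estimated correlation; 0.0502 without spleen WT 2). The call ended too with limma, with only the WT libraries in the fit, after thinning, without the mitochondrial, ribosomal and receptor genes and without the libraries that stand apart (0.0502 to 0.153). Its sign was reversed at 10 CPM or more in 3 libraries, and its p ran from 0.00285 to 0.940 over the alternatives.

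In ∆Foxp3, where the alleles differ between the tissues by the genotype labels but not by the protocol, Rgs2, a regulator of G protein signalling, was higher in lung by 4.92 ± 0.49 on the log2 scale (adjusted p = 0.000267). Tnfaip3 was higher in lung by 2.64 ± 0.27 (adjusted p = 0.000251) and Gadd45b, a stress-response gene, by 3.01 ± 0.44 (adjusted p = 0.00756). Hspa1b was at 0 counts in spleen and at 29.2 ± 23.9 CPM in lung, at least 152-fold higher (adjusted p = 0.00421), with reads that can be shared with Hspa1a. Of 28 immediate early genes, 9 were higher and 0 lower, and 21 and 0 adjusted over the list alone, with Klf6 at 1.66 ± 0.19 (camera adjusted p = 1.0e-41; adjusted p = 0.0231 with an estimated correlation, the single list call of any comparison that held). Of 15 heat shock and dissociation stress genes, 4 were higher, and 7 adjusted over the list alone (camera adjusted p = 8.3e-16; adjusted p = 0.097 with an estimated correlation). Of 30 Treg signature genes, 3 were higher, with 8 higher and 1 lower adjusted over the list alone, among them Rgs1 at 2.04 ± 0.27 (camera adjusted p = 1.3e-09; adjusted p = 0.13 with an estimated correlation). Of 36 cell cycle genes, 0 passed by edgeR, also adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma called 0 (camera adjusted p = 0.967). Camera called the list higher in lung without spleen ∆Foxp3 2 (adjusted p = 0.00829) and lower without spleen ∆Foxp3 3 (3.9e-06), within 3.9e-06 to 0.986 over the alternatives.

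Slc40a1, the iron exporter of macrophages, had 2 counts over the lung ∆Foxp3 libraries and 87.6 ± 51.2 CPM in spleen ∆Foxp3, a ratio of 637 (95% counting interval 176 to 5261; adjusted p = 0.00152). Of 14 monocyte, macrophage and dendritic cell markers, 3 were lower in lung, and 9 adjusted over the list alone (camera adjusted p = 1.6e-12; adjusted p = 0.097 with an estimated correlation). The calls of these 3, Csf1r, Adgre1 and Mrc1, were all lost without lung ∆Foxp3 1, 2 or 3 (adjusted p of up to 0.103, 0.0927 and 0.141 over the alternatives), and the last 2 also without spleen ∆Foxp3 1. The summed lung epithelium markers were 17.5 to 38.0 CPM in spleen ∆Foxp3 and 27.8 to 39.5 CPM in lung ∆Foxp3. Of 8 such genes, 0 passed by edgeR, with 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma, and 1 was higher in lung adjusted over the list alone. Camera called this list higher in lung (adjusted p = 0.0277; adjusted p = 0.13 with an estimated correlation). The call ended without spleen ∆Foxp3 2 (0.101), without the libraries that stand apart (0.0714), at 10 CPM or more in 3 libraries (0.911), with limma (0.263) and after thinning (0.147). With only the ∆Foxp3 libraries in the fit its sign was reversed (0.905; 0.00425 to 0.911 over the alternatives). In all, 96 genes differed, 73 higher and 23 lower in lung, and their groups did not overlap; 15.5% of all tested genes did not, where chance gives 10%. The count was 152 without spleen WT 1 (113 higher, 39 lower), 42 without spleen ∆Foxp3 1 (35 and 7), and 59, 48 and 43 without lung ∆Foxp3 1, 2 and 3 (52 and 7, 43 and 5, 38 and 5). Without spleen ∆Foxp3 2 it was 131, 75 higher and 56 lower, or 57.3% higher. It was 66 without spleen ∆Foxp3 3 (48 and 18) and 69 without lung WT 2 (55 and 14). In both genotypes, 32 genes were higher and 9 lower in lung, 41 in all, against 2.26 and 0.237 by chance (Fisher's exact test, p = 2.5e-29 and 7.3e-13), and 2 were called in opposite directions. The limits given for Fisher's test on the genotype overlap hold here too. The 41 became 25 without spleen WT 2, 26 without spleen WT 3, 19 without spleen ∆Foxp3 1, 25 without lung WT 2, and 25, 24 and 20 without lung ∆Foxp3 1, 2 and 3.

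Whether the genotype difference itself differed between lung and spleen was tested as an interaction. Gt(ROSA)26Sor, a noncoding transcript of the Rosa26 locus (chromosome 6, 113067428 to 113077333, antisense to and partly overlapping Thumpd3), fell by 5.85 ± 0.43 in spleen ∆Foxp3 and was at 0.66 ± 0.32 in lung (interaction 6.51 ± 0.54, adjusted p = 5.5e-05). The strand setting of the counts is not given, so reads of overlapping genes cannot be told apart there. Egr2 was at 0.26 ± 0.36 in spleen and rose by 6.23 ± 0.54 in lung (interaction 5.97 ± 0.66, adjusted p = 0.000758). Btg2, an antiproliferative gene, fell by 2.17 ± 0.23 in spleen (adjusted p = 1.3e-05) and was at 0.82 ± 0.22 in lung (adjusted p = 0.0171), with an interaction of 2.98 ± 0.32 (adjusted p = 0.000496). Its lung difference did not pass without lung WT 2 (adjusted p = 0.0786), lung WT 3 (0.0679) or lung ∆Foxp3 3 (0.0837), or with only the lung libraries in the fit (0.0542). Ctse fell by 3.30 ± 0.27 in spleen and was at 0.37 ± 0.27 in lung (interaction 3.66 ± 0.38, adjusted p = 0.000496). Of 36 cell cycle genes, 14 had a smaller rise in lung, and 32 adjusted over the list alone, with Kif11 at an interaction of −3.08 ± 0.40 (camera adjusted p = 2.7e-55; adjusted p = 0.0764 with an estimated correlation). Of 28 immediate early genes, 3 had a positive interaction, and 8 adjusted over the list alone (camera adjusted p = 5.1e-17; adjusted p = 0.0764 with an estimated correlation). Of 8 erythroid and platelet markers, 1 had a negative interaction, and 7 adjusted over the list alone (camera adjusted p = 4.6e-10; adjusted p = 0.141 with an estimated correlation). Of 14 monocyte, macrophage and dendritic cell markers, 0 passed by edgeR, with 7 at an unadjusted p under 0.05, 2 called by DESeq2 and 1 by limma. Adjusted over the list alone, 5 had a negative interaction (camera adjusted p = 2.1e-06; adjusted p = 0.306 with an estimated correlation). In all, 123 genes passed, 19 with a positive and 104 with a negative interaction. The count was 72 without spleen WT 2, 49 without spleen ∆Foxp3 1, 68 and 52 without lung WT 2 and 3, and 36, 69 and 54 without lung ∆Foxp3 1, 2 and 3.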

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

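The tests on Gt(ROSA)26Sor and the assignments of tissue within genotype were chosen only after the results were seen. Results are given here because the difference between ∆Foxp3 and WT differed between lung and spleen by the interaction test (edgeR). In all, 123 genes passed it. Of 100 assignments of the 12 libraries to the 4 groups, 1, the real one, called as many genes, and the highest other called 95. These fits hold the genotype difference in their spread, so they exclude nothing. Of 100 assignments of tissue within genotype, 2 called as many, a share under 0.05. They were the real one and the one with the tissue names swapped in 1 genotype alone, which called 610 and measures the tissue difference common to both genotypes. The highest of the rest called 119, a narrow margin, and the real count was 36 to 178 with a library left out. Assignments that mix the tissues hold the tissue difference in their spread, so this share cannot decide on chance either.

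Gt(ROSA)26Sor had an interaction of 6.51 (log2, lung minus spleen), with 0.955 ± 0.423 CPM in spleen ∆Foxp3 and 58.9 ± 17.1 CPM in spleen WT (SD, n = 3). A change of the whole chromosomal region is argued against by the neighbours, since the lower of the log2 fold changes of Thumpd3 and Setd5 in spleen was 0.38. The R26.YFP allele, which the labels give to the spleen ∆Foxp3 mice alone, stays open as an explanation and was not tested: that 3 of the 3 libraries of that group lay below all 9 others (1.29 CPM at most against 7.54 CPM at least) is the pattern itself. By the genotype labels, the allele and the group are the same 3 libraries, so it and a genotype difference that depends on the tissue cannot be told apart. The protocol names only the other ∆Foxp3 allele, and the other results of the interaction share this limit.

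Other named genes with a positive interaction were Egr2 at 5.97, Ctse at 3.66, Btg2 at 2.98, Tnf at 2.97, Egr1 at 2.12, Hilpda at 1.95, Dusp6 at 1.94, Ccr8 at 1.71, Cish at 1.47, Socs2 at 1.26 and Swap70 at 1.11. Those with a negative interaction were Lad1 at −5.92, Kif4 at −5.02, Esco2 at −4.42, Cip2a at −4.03, Exo1 at −3.90, Cenpf at −3.87, Brca1 at −3.84, Gcnt1 at −3.81, Nfil3 at −3.19, Kif11 at −3.08, Yod1 at −2.84, Ccna2 at −2.58, Cdc20 at −2.34 and Stmn1 at −2.27. With Gt(ROSA)26Sor, the calls of Egr2, Ctse, Btg2, Egr1, Hilpda, Cish, Lad1, Kif11 and Yod1 were kept in every alternative run. Those of Ccna2, Kif4, Esco2, Brca1, Dusp6, Cdc20 and Stmn1 were lost in 1 or 2 alternatives, with an adjusted p of up to 0.109 (Cdc20, without the libraries that stand apart). Without lung ∆Foxp3 1, Esco2, Brca1, Dusp6, Cdc20 and Stmn1 did not pass (0.0511 to 0.0542). The others were lost in 8 to 15 of 26 alternatives, with adjusted p of up to 0.102 (Cip2a), 0.106 (Socs2), 0.127 (Tnf), 0.135 (Nfil3), 0.147 (Swap70), 0.157 (Ccr8), 0.175 (Exo1), 0.197 (Cenpf) and 0.249 (Gcnt1).

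The lists that camera called for the interaction had median log2 interactions of 1.73 (T helper cytokines), 0.97 (immediate early genes), 0.58 (Treg signature), 0.58 (interferon gamma response), 0.22 (heat shock and dissociation stress) and 0.21 (IL-2 and STAT5 targets). Of the 13 cytokines, 1 passed, and their mean was 0.70. Medians were negative for cell cycle (−2.29), Th17 program (−1.76), glycolysis and hypoxia (−0.37), monocyte, macrophage and dendritic cell (−3.92) and erythroid and platelet (−8.0) genes. Some of these are fitted values of genes at 0 in a group, which have no measured fold. Without such genes the medians were 1.89 for T helper cytokines (5 of 13 left out), 0.19 for heat shock, −1.84 for Th17, −3.72 for monocyte, macrophage and dendritic cell and −7.86 for erythroid and platelet genes. With an estimated correlation none of these 11 calls held, the smallest adjusted p being 0.0734. The heat shock call was lost without spleen WT 1 (adjusted p = 0.785), spleen ∆Foxp3 3 (0.313), lung WT 1 (0.0751) or lung ∆Foxp3 3 (0.198).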

How the results depend on the processing

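The alternatives that leave out Gm10800 and Gm10801, or the 3 libraries that stand apart, were chosen after seeing the data. Counts are given in the order spleen genotype, lung genotype, tissue in WT, tissue in ∆Foxp3, interaction, average, genotype overlap and tissue overlap. Against a fold of 1.5 they were 1648, 932, 235, 38, 50, 2131, 649 and 14. With no low-count filter the tissue and interaction counts were 957, 292 and 363 and the tissue overlap 103. They were 1024, 231, 301 and 88 with DESeq2, and 1064, 260, 219 and 81 with limma, which called 4627 genes in the lung genotype and 4115 in the spleen genotype. With only the groups compared, spleen fell to 2287 and lung rose to 3922, so lung lay above spleen, as it did with limma. Without the libraries that stand apart lung fell to 1321 and the genotype overlap to 995. In that order, leaving out each library gave 2710 to 3575, 1457 to 3364, 281 to 693, 42 to 152, 36 to 178, 4559 to 5640, 1146 to 2148 and 19 to 41. Fewer libraries lower the power of such fits; otherwise the cause was not tested. Among 10 splits of 6 libraries, which are too few for a share under 0.05, the real one alone (1 split) called as many, with 3540 genes in spleen, 2686 in lung and 549 for the tissue in WT against 0 in the highest other, and 96 for the tissue in ∆Foxp3 against 1. Every other split mixes the groups compared and holds their difference in its spread, so its count is not a level of false calls. For the average, 1 of 100 assignments, the real one with 5209 genes, called as many and the highest other 1019. This share, under 0.05, argues against chance between these libraries but does not exclude it.

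Whether the replicate numbers pair the libraries stays open, since the labels do not say and these weak correlations cannot decide it. In 0 of 6 pairs of groups was every same-number correlation over 0.1 (−0.0920 to 0.0955). At most 2 of 3 libraries matched best with their own number. This was so between spleen and lung in WT (same-number values −0.0184 to 0.0457) and in ∆Foxp3 (0.0112 to 0.0955). With the replicate block the counts were 3314, 2422, 511, 83, 74, 4978, 1687 and 39, and the follicular helper list passed in spleen (adjusted p = 0.0406).

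Signs reversed in these cases. Apart from a change in list members named below, the cause was not tested. Slc4a1 in spleen was at −0.54 without spleen ∆Foxp3 1 (adjusted p = 0.828) and at up to 10.13 without another library. Spleen ∆Foxp3 1 held 0.0359% hemoglobin counts, and spleen ∆Foxp3 2 and 3 held 0.000825% and 0.00132%. As signed −log10 of the camera adjusted p, lung epithelium was at −0.0267 for the tissue in WT at 10 CPM or more and at −0.0436 for the tissue in ∆Foxp3 with only the groups compared, cell cycle at −5.41 to 2.08 for the tissue in ∆Foxp3 without each library. Heat shock was at −0.27 and mitochondrial genes were at −1.52 for the interaction without the libraries that stand apart. B and plasma cell markers were at 0.0456 for the average without mitochondrial, ribosomal and receptor genes. That last setting itself removes Ighm, the most abundant B and plasma cell marker, so the list compared there is not the same. Of the 79 list calls, 78 were lost with an estimated correlation. Of the called named genes, 77 of 114 kept their call in all alternatives in spleen, 64 kept it in lung, 21 of 48 and 13 of 32 for the tissue in WT and ∆Foxp3, 10 of 27 for the interaction and 83 of 116 for the average. At totals of 3958892 counts and more, 3 counts in a library are 0.332 to 0.758 CPM, and differences near that level were not detectable at this depth.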

Other observations

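The tests of Ighm, and the values without the libraries that stand apart, were chosen only after results were seen. Inhibitory receptors and follicular helper genes shared members that rose in both tissues. Pdcd1, which encodes the inhibitory receptor PD-1, rose by 1.60 ± 0.28 in spleen ∆Foxp3 and by 3.37 ± 0.30 in lung, and Tnfsf8, the ligand of CD30, by 3.99 ± 0.33 and 4.26 ± 0.34. Of 13 co-inhibitory receptors, 5 rose and 2 fell in either tissue, with 5 and 2 in spleen and 6 and 2 in lung adjusted over the list alone. The camera adjusted p was 0.147 in spleen and 0.0202 in lung (adjusted p = 0.258 with an estimated correlation; 0.00125 to 0.178 over the other alternatives, the last with limma). Of 10 follicular helper genes, 5 rose and 2 fell in spleen and 4 and 3 in lung, the same adjusted over the list alone. The camera adjusted p was 0.0740 in spleen and ran from 0.00839 to 0.179 over the alternatives. It passed there with DESeq2 (0.0104), with no low-count filter (0.0213) and without spleen ∆Foxp3 3 (0.00839), lung WT 1 (0.0260) or lung WT 3 (0.0343). In lung it was 0.00338 (adjusted p = 0.257 with an estimated correlation; 0.000419 to 0.257 over the others, the last with limma). Of 8 Th17 genes, 3 rose and 1 fell in spleen (camera adjusted p = 0.117) and 1 rose and 3 fell in lung (0.440), with 4 and 1, and 2 and 4, adjusted over the list alone. In WT Treg, 0 of these 8 passed between lung and spleen by edgeR, with 4 at an unadjusted p under 0.05 and 3 called by DESeq2 and by limma, and 4 were higher adjusted over the list alone (camera adjusted p = 0.00152; adjusted p = 0.0633 with an estimated correlation).

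Homing and adhesion receptors went both ways. In lung ∆Foxp3, 14 of 33 fell and 5 rose, with 17 and 9 adjusted over the list alone, and Itga6, an integrin gene, fell by 2.27 ± 0.23 (camera adjusted p = 0.0179; adjusted p = 0.123 with an estimated correlation). The call was lost without spleen WT 1 (0.108) and without the libraries that stand apart (0.0838), within 0.00172 to 0.108 over the alternatives. In spleen 11 fell and 6 rose, with 14 and 9 adjusted over the list alone (camera adjusted p = 0.254), among the latter Cxcr6, a chemokine receptor gene, at 6.42 ± 0.70. Of 17 IL-2 and STAT5 targets, 3 rose and 6 fell in spleen, 3 and 10 adjusted over the list alone (camera adjusted p = 0.131; 0.0430 without spleen ∆Foxp3 2 and 0.0357 without a low-count filter, the lowest, and up to 0.277 over the alternatives). In lung 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.468), with a median of −0.08 and a mean of 0.46. Pim1, a kinase gene, fell by 1.53 ± 0.17 and 1.45 ± 0.16. Of 23 apoptosis regulators, 5 rose and 4 fell in spleen and 5 and 6 in lung, with 6 and 6, and 8 and 6, adjusted over the list alone (camera adjusted p = 0.765 and 0.433), the lung median being −0.18 and the mean 0.38. Of 32 oxidative phosphorylation genes, 14 rose in spleen and 6 in lung, and 14 and 9 adjusted over the list alone, with Cox5a at 0.81 in both (camera adjusted p = 0.00157 and 0.000349; adjusted p = 0.669 and 0.551 with an estimated correlation). Of 22 cholesterol synthesis genes, 1 rose and 4 fell in spleen and 2 and 2 in lung, the same adjusted over the list alone (camera adjusted p = 0.0815 and 0.362). The spleen value passed without spleen WT 1 (0.0336), spleen ∆Foxp3 2 (0.000769), the libraries that stand apart (0.0439) or a low-count filter (0.00488) and with limma (0.0111), within 0.000769 to 0.251 over the alternatives.

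Of 15 heat shock and dissociation stress genes, 2 rose and 1 fell in spleen (camera adjusted p = 0.752; median 0.44, mean −0.23) and 2 rose in lung, all likewise adjusted over the list alone. The lung call (camera adjusted p = 0.0201; adjusted p = 0.551 with an estimated correlation) was lost without spleen ∆Foxp3 1 (0.0646), lung WT 2 (0.0958), lung ∆Foxp3 3 (0.239) or the libraries that stand apart (0.108), within 0.00336 to 0.239 over the alternatives. Of 30 ribosomal protein genes, 1 rose and 4 fell in spleen, with 1 and 2 adjusted over the list alone (camera adjusted p = 0.147). That p was 0.0407 without spleen WT 2, 0.0273 without spleen WT 3, 0.0456 without spleen ∆Foxp3 3 and 0.0151 without a low-count filter, within 0.0151 to 0.779 over the alternatives. In lung, 0 of the 30 passed by edgeR, with 3 at an unadjusted p under 0.05 and 1 called by DESeq2 and 6 by limma (camera adjusted p = 0.760). Of 11 mitochondrial genes, 1 rose in either tissue, also adjusted over the list alone (camera adjusted p = 0.938 and 0.886). Of 5 NK, innate lymphoid and gamma-delta T cell markers, 1 rose in spleen and 2 in lung, with 1 higher, and 3 higher and 1 lower, adjusted over the list alone (camera adjusted p = 0.563 and 0.155). The lung p was 0.0452 without lung WT 1, 0.0201 without lung ∆Foxp3 1 and 0.0301 without lung ∆Foxp3 2. It was 0.0132 without a low-count filter and 0.0380 without the mitochondrial, ribosomal and receptor genes, within 0.0132 to 0.635 over the alternatives. Gzma is among them and in the cytotoxic list too. Of 14 monocyte, macrophage and dendritic cell markers, 4 were higher and 1 lower in spleen ∆Foxp3 and 1 lower in lung, with 5 and 1, and 1 lower, adjusted over the list alone (camera adjusted p = 0.131 and 0.136). The first was 0.0113 without spleen ∆Foxp3 2, 0.0169 without the libraries that stand apart, 0.00172 without a low-count filter and 0.00844 with limma (0.00172 to 0.543 over the alternatives). The second was 0.0163 without lung WT 2, 0.00954 without lung WT 3, 0.0481 without lung ∆Foxp3 3, 0.0050 without a low-count filter and 0.0334 with DESeq2 (0.0050 to 0.830). Of 8 erythroid and platelet markers, 2 were higher in spleen ∆Foxp3, also adjusted over the list alone (camera adjusted p = 0.254; 0.0179 without spleen ∆Foxp3 2, 0.00131 without a low-count filter, and up to 0.847 over the alternatives). Of 6 endothelium markers, 1 was higher and 2 were lower in spleen ∆Foxp3, also adjusted over the list alone (camera adjusted p = 0.219; 0.0496 at 10 CPM or more in 3 libraries, and up to 0.560 over the alternatives). Of 4 fibroblast and smooth muscle markers, 1 was higher in either tissue, and in spleen 1 was lower too adjusted over the list alone (camera adjusted p = 0.468 and 0.932; in spleen 0.0495 with only its libraries in the fit, and up to 0.847 over the alternatives). Of 8 lung epithelium markers, 2 were higher and 2 lower in spleen and 1 and 3 in lung, with 3 and 2, and 1 and 3, adjusted over the list alone (camera adjusted p = 0.785 and 0.433). Of 2 CD8 T cell markers, 0 passed in either tissue by edgeR, DESeq2 or limma, with 0 in spleen and 1 in lung at an unadjusted p under 0.05 (camera adjusted p = 0.787 and 0.692). The 1 neutrophil marker tested did not pass either, also unadjusted (0.703 and 0.939). No mast cell, basophil and eosinophil marker was tested, its 11 genes summing to 4.68 CPM at most.

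Ighm, the gene of the constant region of the immunoglobulin mu chain (chromosome 12, 113418558 to 113422730), was at 1088 to 1939 CPM in the 6 WT libraries and at 50.5 to 231 CPM in the 6 ∆Foxp3 libraries. B or plasma cells as the main source of its level are argued against by their other abundant transcripts. Igkc, Cd79a and Ms4a1 summed to at most 2.17% of Ighm in any WT library. Igkc and Cd79a were themselves higher in WT, however. Igkc was at 5.36 to 22.9 CPM in WT and at 0 to 2.77 CPM in ∆Foxp3, and Cd79a at 3.88 to 7.77 CPM and 1.43 to 2.77 CPM. Ms4a1 overlapped, at 0 to 2.11 CPM and 0 to 0.447 CPM. A small share of RNA from B or plasma cells in the WT libraries is thus not argued against. The gate on TCRβ and CD4 would remove such cells. After thinning to 1 total, Ighm differed by −3.49 in spleen and −3.57 in lung (edgeR adjusted p = 1.5e-05 and 2.7e-05). At 1088 CPM or more in WT, thinning could hardly have removed such a difference, so this is a weak test of depth. Transcription of Ighm in the sorted cells that depends on the genotype stays open as a hypothesis and was not tested.

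Of 14 monocyte, macrophage and dendritic cell markers, 3 (Csf1r, Adgre1 and Mrc1) were higher in spleen ∆Foxp3 than in lung ∆Foxp3 and 11 did not pass (camera adjusted p = 1.6e-12; adjusted p = 0.097 with an estimated correlation). All 3 calls were lost without lung ∆Foxp3 1, 2 or 3, and those of Adgre1 and Mrc1 also without spleen ∆Foxp3 1, with adjusted p of up to 0.103, 0.0927 and 0.141 over the alternatives. Of 10 further macrophage genes listed before their values were seen, 7 lay higher in all 3 spleen than in all 3 lung ∆Foxp3 libraries, among them Apoe, at 16.3 to 457 CPM against 7.53 to 9.23 CPM, and Fcna, at 4.31 to 66.0 CPM against 0. This is consistent with RNA of splenic macrophages in the spleen libraries, although the gate on TCRβ, CD4 and GFP would remove such cells. Whether the tissue or the allele also changes these genes in Treg stays open, and the preparation, with magnetic enrichment for the lungs alone, is the same split. In WT, C1qb, a macrophage gene, was at 48.2, 6.61 and 5.25 CPM in spleen and at 0 in lung (edgeR adjusted p = 0.0262, and up to 0.200 over the alternatives). The camera adjusted p of the 14 markers between lung and spleen WT ran from 0.00988 to 0.959 over the alternatives. Of 9 detected genes of a red cell precursor list written in the same way, 4 were higher in all 3 lung WT than in all 3 spleen WT libraries, among them Fech, at 68.6 to 103 CPM against 30.1 to 47.2 CPM.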
